A study of Mus musculus with 8 samples.

How the data were processed

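Ly6C-high monocytes were sorted from the blood of C57BL/6J mice, and total RNA was made into bulk RNA-seq libraries with a SMARTer kit, which copies polyadenylated transcripts from end to end, per the labels' protocols. The labels gave 3 libraries of continuously fed mice and 3 of mice fasted for 24 h and refed for 4 h. They also named 1 fed and 1 refed droplet single-cell library. The title of each bulk library gave its group and a number, and the columns of the deposited table were matched to the titles by name.

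The deposited table held estimated counts per gene, merged over samples from salmon, per the name the labels give the file. About 17.0% of its values were not whole, and they were rounded to whole numbers. The annotation behind the counts, the salmon version and the strand setting were not given in the sources used here. The submitters' processing notes name Cell Ranger 6.1.2 and the genome builds GRCm39 and mm10, without saying which build served which assay. The table listed 32285 gene identifiers, the same set as in the deposited single-cell feature list, which supplied all 32285 symbols. For the 38 symbols carried by more than 1 identifier, the identifier with the most counts kept the plain symbol. Coordinates, transcript lengths and sequences came from GENCODE M21 on GRCm38. A gene's length was the median over its protein-coding transcripts, or over all its transcripts where none was protein-coding. Salmon divides reads between similar transcripts, so values of close paralogs such as Hba-a1 and Hba-a2, Ly6c1 and Ly6c2, or Chil3 and Chil4 are uncertain in how they are split. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be separated either.

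Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 11953 genes. Libraries were scaled by TMM, and refed was compared with fed by the quasi-likelihood F-test with an intercept and a group term. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and the threshold was 0.05. Standard errors were derived from the F statistic and the unshrunken fold change. Levels are TMM-normalised CPM, as mean ± SD over 3 libraries. Summed levels of marker lists and the highest T cell marker value are CPM of library totals without TMM.

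Before the data were examined, 31 gene lists were fixed, covering monocyte subsets, other blood cells, trafficking, hormone and clock responses, immunity and metabolism. Each list with at least 5 tested members was tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over 28 lists. The same test with an estimated correlation, and fry, were alternatives. For each list, members past the gene test were counted over all genes and again adjusted over the list alone. Genes named in the text also followed a rule fixed beforehand. It took the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 2 and groups that did not overlap, without unnamed gene models and pseudogenes. It added up to 4 members of each list with the smallest adjusted p, and Ly6c2, Ccr2, Cxcr4, Cx3cr1, Tsc22d3, Fkbp5, Per1, Nr4a1 and Il1b whether or not they passed. Some genes that the rule takes are not reported here. A few other genes, said below to be chosen after their values were seen, were added.

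Shares of counts were compared by a two-sided exact permutation test, which with 3 against 3 libraries cannot go below p = 0.1. Replicates differed by more than counting error in each pair of the same group, with a chi-square per degree of freedom between 14.8 and 53.6, so no library was counted as a repeat of another. Total estimated counts per library lay between 20069854 and 28066347. On simulated counts for the comparison of refed with fed, with 200 of 11830 tested genes changed, the edgeR test called 29 of 67 genes changed 1.5-fold, 62 of 67 changed 2-fold and 66 of 66 changed 3-fold, with 15 false calls among 172. With no change simulated it called 0 genes.

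Alternatives fixed beforehand were other scalings (DESeq2 size factors, upper quartile, library size only), DESeq2 1.42.0, limma-voom with and without quality weights, other low-count filters, a replicate number term, a threshold of 0.1, a test against a fold change of 1.5, and each library left out in turn. Removing the trend of each library on transcript length, or on GC content, by a smooth curve entered as an offset was added after the fold changes had been seen to follow length. In simulated counts with such a length trend, 90 unchanged genes were called without the correction and 18 with it. The simulated trend used the same gene lengths, so it could not show errors in them. The single-cell matrix was not used here, and its barcodes were only counted.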

Results

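Circulating Ly6C-high monocytes, the classical monocytes that leave the blood for inflamed tissue, were profiled by bulk RNA-seq in continuously fed mice and in mice that had fasted for 24 h and eaten again for 4 h. Each group had 3 libraries. Total estimated counts were 25134906, 23397504 and 28066347 in fed libraries 1 to 3, and 23199470, 22252084 and 20069854 in refed libraries 1 to 3. Between 15157 and 15590 genes had at least 1 count per library. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries only. The comparison addresses how feeding state changes the monocytes found in blood, in a study of where monocytes go during a fast. No bulk library came from mice fasted without refeeding, so effects of the fast and of the refeeding cannot be told apart.

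Monocytes taken after refeeding held more transcript of the secreted chitinase-like protein gene Chil3, the matrix protein gene Fn1 and the phagocytic receptor gene Cd93 than monocytes of fed mice. They held less of Ace, Treml4 and other markers of non-classical monocytes, less of the MHC class II genes, including Cd74, and less of some interferon-responsive genes, such as Ifi27l2a. Chil3 went from 2838 ± 414 to 12074 ± 1440 CPM and Ace from 528 ± 207 to 116 ± 25.5 CPM (SD, n = 3 per group). Of 11953 genes tested with edgeR, 1189 changed, 754 of them higher and 435 lower in refed monocytes. In 1188 of these the 3 refed libraries lay on one side of the 3 fed libraries, which chance gives for 10% of genes and which held for 33.7% of all genes tested. With upper-quartile scaling the split was 595 higher and 571 lower, and with library size only it was 540 higher and 635 lower. The count was 333 without fed 1, 781 without fed 2, 165 without fed 3, 406 without refed 1, 280 without refed 2 and 1713 without refed 3. Genes higher in refed had long transcripts: 414 of the 754 were among the 2389 genes with the longest transcripts, against 24 of the 435 lower genes. After removal of each library's trend on length, 403 genes were higher and 331 lower, and 626 of the 1189 genes kept their call. Of 28 gene lists tested, camera called 16 with the preset correlation. With an estimated correlation camera called 0 (1 at an unadjusted p under 0.05), and fry called 2.

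**Figure D1:**
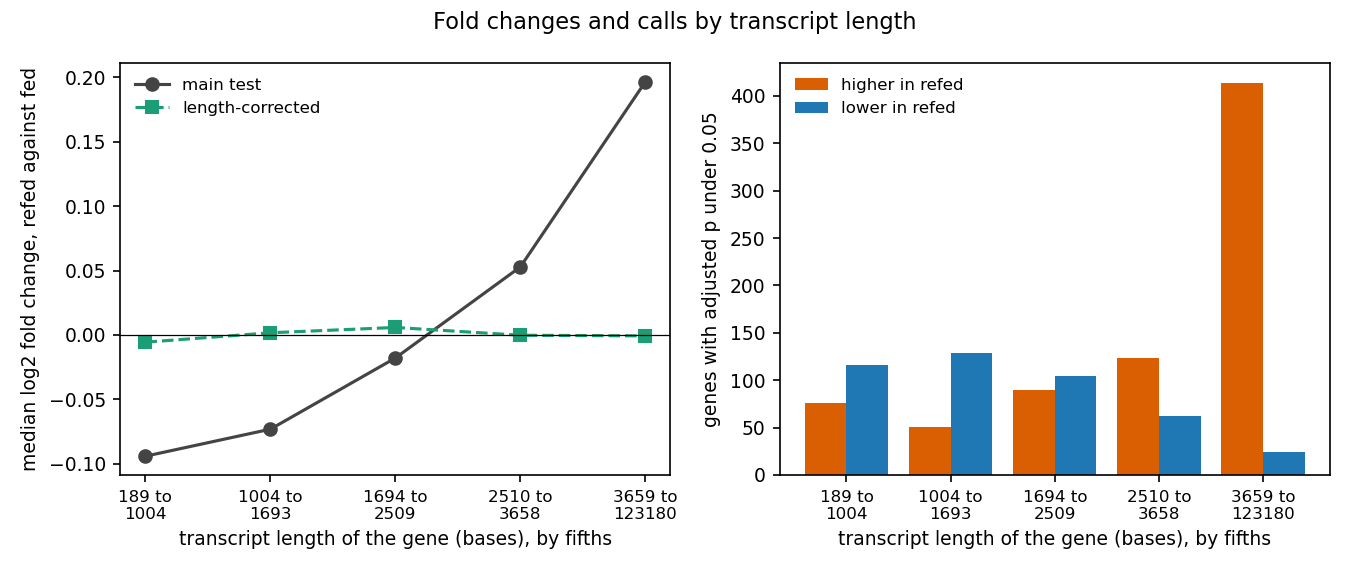
Left, median log2 fold change of refed against fed monocytes in 5 equal bins of transcript length (bases), in the main test (circles) and after length correction (squares). Right, number of genes higher (orange) or lower (blue) in refed at an edgeR adjusted p under 0.05 in the same bins of the main test; the median ran from −0.09 in the shortest bin to 0.20 in the longest, where 414 genes were higher and 24 lower.

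Among the 12 largest rises, the largest by fold was that of Lars2, which encodes the mitochondrial leucyl-tRNA synthetase (GRCm38 chromosome 9, 123366927 to 123462666, plus strand). Its log2 fold change was 2.84 ± 0.20 (SE, n = 3 per group, edgeR adjusted p = 0.00201), from 346 ± 30.4 to 2469 ± 729 CPM. Its transcript shares a 52-base run of sequence with the antisense RNA gene Gm15564, chosen after its values were seen, which rose by nearly as much (log2 fold change 2.72 ± 0.29, adjusted p = 0.00584). Reads from this run could give both rises, so the rise counted for Lars2 may not be one of its own transcript. Chil3 (chromosome 3, 106147554 to 106167564, minus strand) rose by 2.09 ± 0.13 on the log2 scale (adjusted p = 0.00172), and its close paralog Chil4, also chosen after its values were seen, was at 3.40 ± 0.53 CPM in refed. The scavenger receptor gene Stab1 rose from 3.21 ± 2.02 to 17.9 ± 8.95 CPM (adjusted p = 0.0263) and Plppr3 from 5.32 ± 2.56 to 27.1 ± 7.37 CPM (adjusted p = 0.00971). Hivep2, Slc4a1 (the red cell anion exchanger), the immediate early gene Egr1, Tent5c, Ksr1, the complement C5a receptor gene C5ar2, the retinol metabolism gene Dhrs3 and Adgrg6 completed the 12, with log2 fold changes between 1.62 and 1.80. Of the 12 calls, 5 were kept without fed 1, 11 without fed 2, 4 without fed 3, 11 without refed 1, 6 without refed 2 and 12 without refed 3. After length correction 10 were kept, and Hivep2 and Egr1 were lost (adjusted p = 0.0567 and 0.0564). The log2 fold change of Hivep2 went from 1.80 ± 0.33 to 1.40 ± 0.35, and that of Egr1 from 1.79 ± 0.41 to 1.69 ± 0.42.

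Among the 12 largest falls under the same rule, which leaves out genes of low level, Ace, the angiotensin-converting enzyme gene (chromosome 11, 105967945 to 105989964, plus strand), came first. It fell by 2.19 on the log2 scale (SE 0.31, n = 3 per group, edgeR adjusted p = 0.0092). Next were Lilra5, an activating leukocyte receptor gene, from 8.84 ± 2.97 to 1.94 ± 0.64 CPM, and the Ly6 family gene Ly6i, from 34.3 ± 8.22 to 8.21 ± 0.90 CPM. Sqle, encoding squalene epoxidase of the cholesterol pathway, went from 19.0 ± 10.6 to 4.65 ± 1.53 CPM, with an adjusted p of 0.0357. Eno3, Tppp3, the checkpoint receptor gene Havcr2 and Cd300e fell as well. So did the nuclear receptor gene Pparg, the integrin gene Itgax (CD11c), Nr1h3 (the oxysterol receptor LXRα) and the Notch target Nrarp. The log2 fold changes of these last 8 lay between −2.01 and −1.82. Without fed 1, fed 2 and fed 3, 7, 12 and 6 of the 12 kept the call. Without refed 1, refed 2 and refed 3, 10, 7 and 12 kept it. Limma-voom called 10 of the 12, without the gene Sqle (adjusted p = 0.0859) and the gene Pparg (0.0642).

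**Figure D2:**
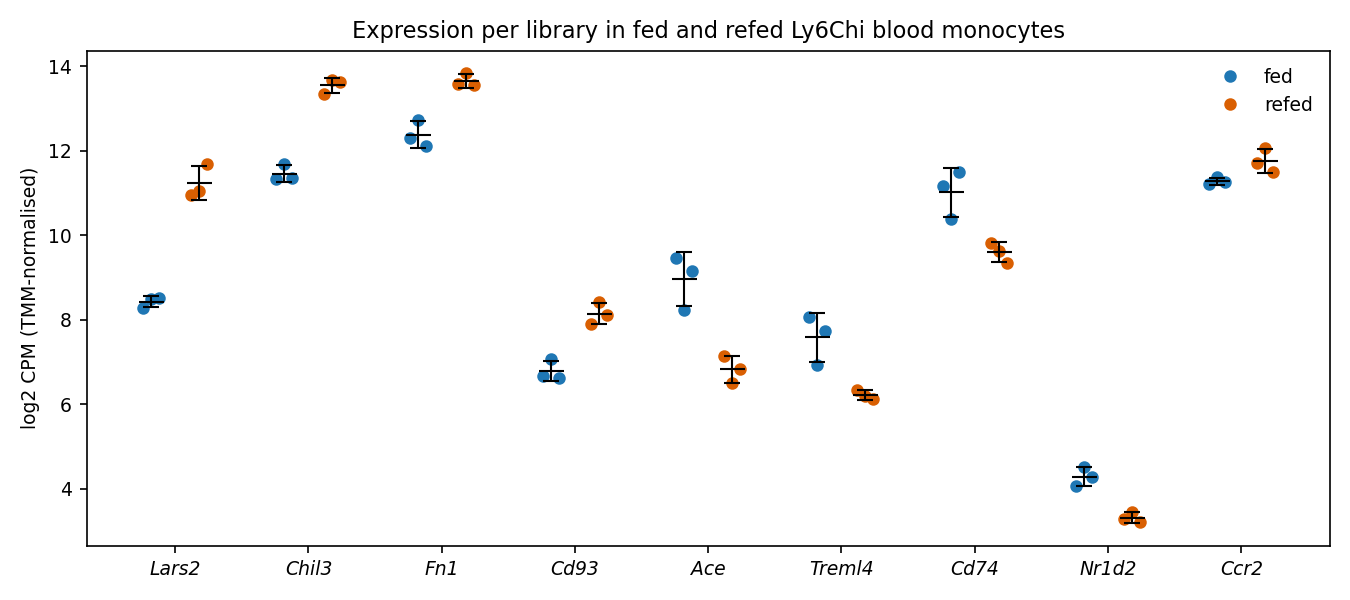
log2 CPM (TMM-normalised) of 9 genes in each of the 3 fed (blue) and 3 refed (orange) libraries, with the mean and SD of the log2 values as black bars. The 3 refed libraries lie above the 3 fed ones for Lars2, Chil3, Fn1, Cd93 and Ccr2 and below them for Ace, Treml4, Cd74 and Nr1d2. Of these, Ccr2, from 2487 ± 146 to 3519 ± 703 CPM, did not pass the test (edgeR adjusted p = 0.058).

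Markers of non-classical monocytes, the patrolling Ly6C-low subset, fell as a group. Of the 18 tested, 11 fell, 0 rose and 7 did not pass, with a median log2 fold change of −1.15 (15 fell when adjusted over the list alone). Examples besides Ace, Eno3 and Itgax were Treml4, from 202 ± 74.3 to 75.0 ± 5.93 CPM, and the scavenger receptor Cd36, from 84.1 ± 46.3 to 25.5 ± 7.80 CPM. For Cd36 the groups overlapped, with 32.4 CPM in fed 2 and 34.5 in refed 1 (edgeR adjusted p = 0.0492). The fractalkine receptor gene Cx3cr1 was at 623 ± 83.1 CPM in fed and 656 ± 185 in refed (edgeR adjusted p = 0.847), and the gene Nr4a1, a transcription factor this subset needs, had a log2 fold change of −0.66 ± 0.26 that did not pass (adjusted p = 0.146). Nr4a1 passed with DESeq2 (adjusted p = 0.0327) and without fed 2 (0.0177), while the other left-out libraries gave 0.203 to 0.355. Classical monocyte markers went both ways: of 17 tested, 5 rose, 2 fell and 10 did not pass (8 and 2 when adjusted over the list alone). Chil3, Fn1 (from 5430 ± 1235 to 12911 ± 1454 CPM) and the lipopolysaccharide co-receptor gene Cd14 (from 50.3 ± 8.92 to 110 ± 40.2 CPM) were among those that rose. Plac8, from 767 ± 88.3 to 367 ± 96.4 CPM, and Ms4a4c, from 619 ± 106 to 372 ± 52.4 CPM, fell. Ly6c2, which encodes the antigen used in the sort, did not pass (log2 fold change −0.27 ± 0.24, adjusted p = 0.497). The camera test with the preset correlation called the non-classical list lower (adjusted p = 7.88e-08) and did not call the classical list (adjusted p = 0.116). The first call was lost with an estimated correlation (adjusted p = 0.483). The classical list was called higher without fed 2 (camera adjusted p = 0.0104), without refed 1 (adjusted p = 0.0336) and after length correction (adjusted p = 0.0362). Of the 18 called genes in both lists, 6 were kept without fed 1, 16 without fed 2, 4 without fed 3, 10 without refed 1, 5 without refed 2 and 15 without refed 3, and 15 after length correction. In the same libraries NK cell markers were lower, with a median log2 fold change of −2.10, and MHC class II genes with one of −1.11.

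MHC class II genes, which present peptides to CD4 T cells, were lower in refed monocytes: 8 of 10 fell, 0 rose and 2 did not pass, with a median log2 fold change of −1.11 (10 fell when adjusted over the list alone). The invariant chain gene Cd74 went from 2172 ± 786 to 783 ± 126 CPM (edgeR adjusted p = 0.0169), H2-Ab1 from 472 ± 192 to 145 ± 30.6, H2-Aa from 289 ± 109 to 101 ± 20.7 and H2-Eb1 from 126 ± 49.8 to 44.0 ± 10.4. Most type I interferon response genes had a negative log2 fold change too, but a minority passed over all genes. Of 23 tested, 7 fell, 0 rose and 16 did not pass, with a median of −0.53 (14 fell when adjusted over the list alone). Ifi27l2a went from 200 ± 35.1 to 92.3 ± 13, the transcription factor gene Irf7 from 360 ± 30.2 to 244 ± 17 and Ifit3 from 120 ± 5.86 to 68.2 ± 17.9. Camera with the preset correlation called both lists (adjusted p = 3.62e-07 for each), and neither call held with an estimated correlation (adjusted p = 0.483 for each). Of the 15 called genes, 4 kept the call without fed 1, 12 without fed 2, 2 without fed 3, 8 without refed 1, 2 without refed 2 and 14 without refed 3. The MHC class II genes kept 0 of their 8 calls without fed 1, fed 3 or refed 2. Medians were negative too for markers of other cells that express MHC class II, at −0.63 for B cell markers and −0.46 for dendritic cell markers. Of 8 B cell markers tested, 1 passed, and 2 had a positive log2 fold change. Of 10 dendritic cell markers tested, 3 fell (the tetherin gene Bst2, Kmo and the transcription factor gene Zbtb46) and 7 did not pass (4 fell when adjusted over the list alone). Bst2 is also a member of the interferon list, so its fall is counted in both lists. Limma-voom called 2 of the 10, and the gene Zbtb46 lost its call with limma-voom (adjusted p = 0.06), length correction (0.0607) and GC correction (0.0529). The camera adjusted p of this list was 0.0121, 0.0638 without refed 3, and 0.483 with an estimated correlation.

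Trafficking receptors and adhesion molecules were of interest because monocyte exit and entry depend on them. Of 20 tested, 4 fell, 0 rose and 16 did not pass, with a median log2 fold change of −0.17 (6 fell and 1 rose when adjusted over the list alone). Those that fell were the selectin ligand gene Selplg, from 683 ± 19.7 to 503 ± 7.37 CPM, the integrin genes Itgb2, from 1609 ± 55.5 to 1206 ± 54.9, and Itgal, from 798 ± 134 to 535 ± 19.8, and the sphingosine-1-phosphate receptor gene S1pr5, from 89.2 ± 36.7 to 35.7 ± 8.69. Values per fed library of S1pr5 (125, 52.1 and 90.2 CPM) and Itgal (902, 646 and 844) were lowest in fed 2, as were those of the non-classical marker Ace (711, 302 and 570), and the non-classical list had a median of −1.15. Itgal is itself a member of the non-classical list, so its fall is counted in both lists. The chemokine receptor gene Ccr2, which monocytes need to leave bone marrow, had a log2 fold change of 0.50 ± 0.14 and did not pass (edgeR adjusted p = 0.058). It passed with DESeq2 (adjusted p = 0.00918), limma-voom with quality weights (0.0155), edgeR with no low-count filter (0.0471) and edgeR without refed 3 (0.013), while the other left-out libraries gave 0.0966 to 0.186. Cxcr4, the marrow-retention receptor, was at 30.3 ± 4.27 CPM in fed and 25.9 ± 8.46 in refed (adjusted p = 0.584). The list was called lower (camera adjusted p = 0.0494). It was lost without fed 1, refed 1, refed 2 or refed 3 (adjusted p = 0.108, 0.0779, 0.0623 and 0.267) and with an estimated correlation (adjusted p = 0.483). Among glucocorticoid-induced genes, which respond to the hormone rise of a fast, 1 of 18 passed: Ddit4, an inhibitor of mTORC1, fell from 36.6 ± 8.66 to 19.1 ± 5.20 CPM (adjusted p = 0.046, and 0 genes when adjusted over the list alone). After length correction Ddit4 went from a log2 fold change of −0.94 to −0.89 (adjusted p = 0.0659), which left 0 of the 18 called. The gene Tsc22d3 (GILZ) had a log2 fold change of −0.69 ± 0.20 (adjusted p = 0.07), Fkbp5 of 0.75 ± 0.54 (adjusted p = 0.409) and Per1 of 0.10 ± 0.24 (adjusted p = 0.83), none past the threshold in edgeR. Tsc22d3 passed with DESeq2 (adjusted p = 0.00473), quality weights (0.0317) and no low-count filter (0.0387). The list median was 0.11 (−0.01 after length correction), its mean was 0.33, the camera direction was down, and the list was not called (adjusted p = 0.708). Of the 5 genes called in both lists, 1 was kept without fed 1, 5 without fed 2, 0 without fed 3, 1 without refed 1, 0 without refed 2 and 4 without refed 3.

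Core clock genes changed in opposite directions. Of 15 tested, Clock rose, from 40.8 ± 3.50 to 61.0 ± 3.48 CPM (edgeR adjusted p = 0.0108), 4 fell and 10 did not pass (1 rose and 5 fell when adjusted over the list alone). Nr1d2 (REV-ERBβ), a repressor of the loop, went from 19.7 ± 2.99 to 9.98 ± 0.89 CPM (adjusted p = 0.00978), the PAR bZIP factor gene Tef from 45.1 ± 6.65 to 26.0 ± 2.66 and the orphan receptor gene Rora from 8.07 ± 0.41 to 4.82 ± 0.26. Clock has a long transcript, and its log2 fold change of 0.58 became 0.25 after length correction (adjusted p = 0.0962). The list was called lower (camera adjusted p = 0.0454, and 0.483 with an estimated correlation; fry adjusted p = 0.0149). The camera call was lost without fed 1, refed 1, refed 2 or refed 3 (adjusted p = 0.0579, 0.0864, 0.0546 and 0.0886). Of the 5 called genes, 2 were kept without fed 1, 5 without fed 2, 0 without fed 3, 3 without refed 1, 3 without refed 2 and 5 without refed 3.

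**Figure D3:**
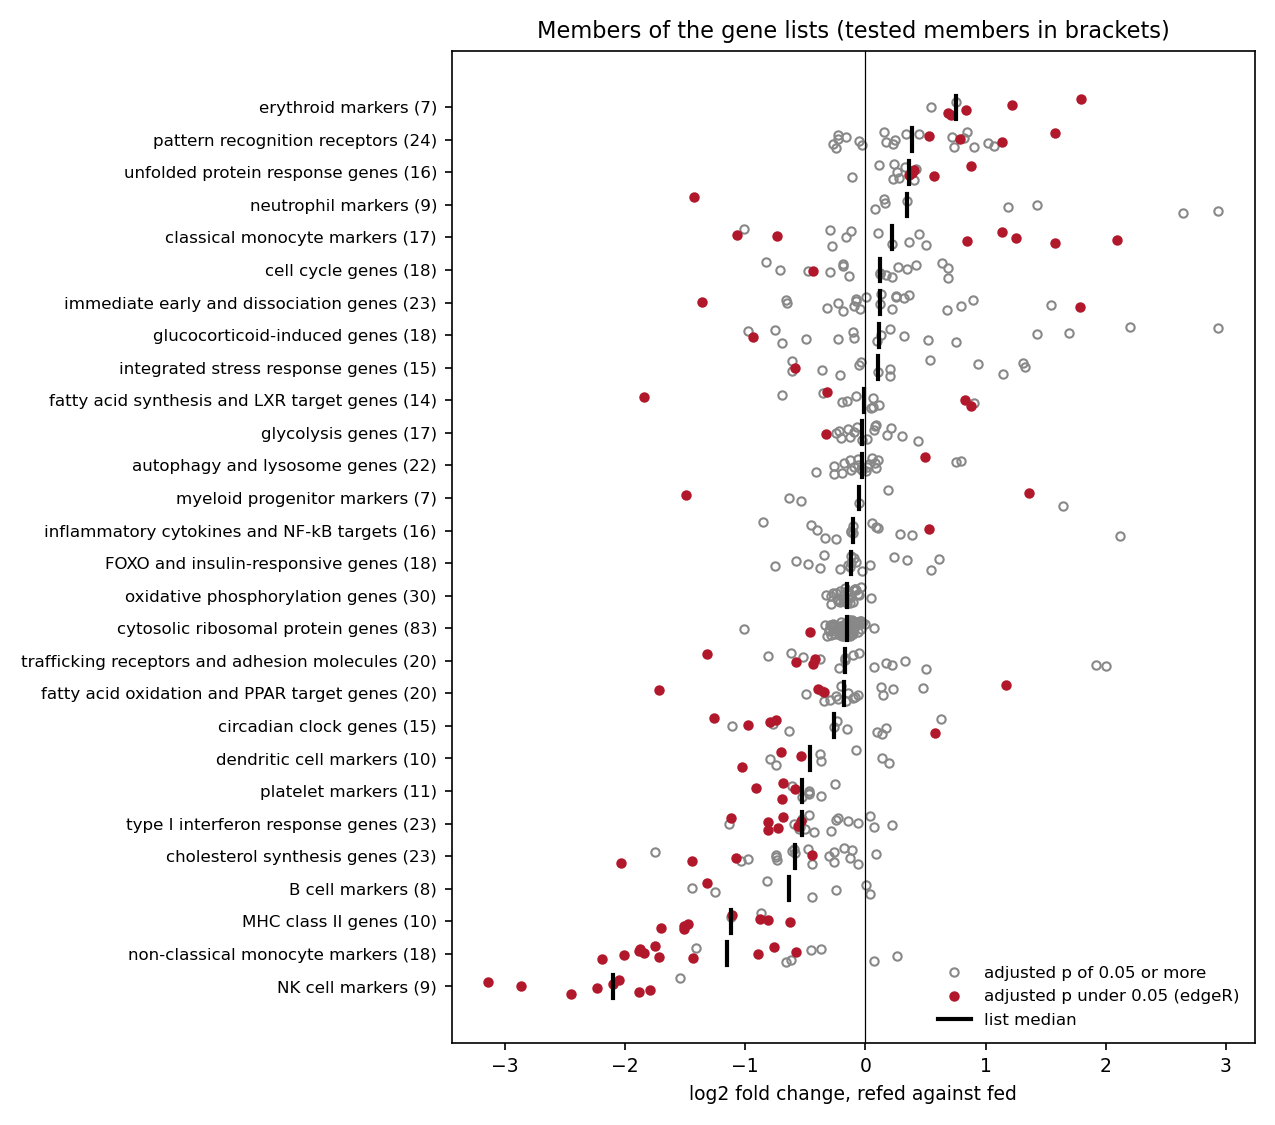
log2 fold change of refed against fed monocytes for each tested member of the 28 gene lists with at least 5 tested members, ordered by list median (black bar); filled red points passed the edgeR test at an adjusted p under 0.05 and open grey points did not. NK cell markers (median −2.10), non-classical monocyte markers (−1.15) and MHC class II genes (−1.11) lie lowest and erythroid markers (0.75) highest.

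Most cholesterol synthesis genes had a negative log2 fold change in refed monocytes, but a minority passed over all genes. Of 23 tested, 4 fell, 0 rose and 19 did not pass, with a median log2 fold change of −0.58 (13 fell when adjusted over the list alone). Besides Sqle these were the lanosterol demethylase gene Cyp51, from 35.3 ± 11.8 to 16.8 ± 2.76 CPM, Mvd, from 32.1 ± 2.48 to 23.5 ± 2.14, and Idi1, from 30.5 ± 14.5 to 11.3 ± 3.25. Fatty acid synthesis and LXR target genes went both ways, with 2 of 14 higher and 2 lower over all genes and over the list alone. The acetyl-CoA carboxylase gene Acaca, from 12.3 ± 0.63 to 22.7 ± 3.09 CPM, and the cholesterol exporter gene Abca1, from 33.1 ± 3.43 to 58.6 ± 11, rose, while Nr1h3 and Lpcat3 fell. Abca1 lost its call after length correction (log2 fold change 0.39 ± 0.11, edgeR adjusted p = 0.086). Among 20 fatty acid oxidation and PPAR target genes, Ppard rose from 2.94 ± 0.85 to 6.59 ± 1.17 CPM. The thiolase gene Acaa2, from 118 ± 2.57 to 89.8 ± 4.00 CPM, Etfa and Cd36 fell (7 lower and 1 higher when adjusted over the list alone). Camera with the preset correlation called the cholesterol list (adjusted p = 1.43e-06) and the oxidation list (adjusted p = 0.00859) lower and not the synthesis list (adjusted p = 0.936). Both calls were lost with an estimated correlation (adjusted p = 0.509 for each). Of the 12 genes called in the 3 lists, 3 were kept without fed 1, 8 without fed 2, 1 without fed 3, 2 without refed 1, 2 without refed 2 and 11 without refed 3. The cholesterol genes kept 0 of their 4 calls without fed 1, fed 3, refed 1 or refed 2, and the oxidation genes 0 of 4 without fed 3, refed 1 or refed 2. Limma-voom called 2 cholesterol genes, and the gene Idi1 (adjusted p = 0.077), the gene Sqle (0.0859) and the gene Cd36 (0.0911) were not called by it. Cd36 was also not called with DESeq2 size factors in edgeR (adjusted p = 0.0503). Length correction kept 7 of the 12. Besides Abca1 it ended the calls of Idi1 (log2 fold change −1.44 before and −1.35 after), Mvd (−0.45 and −0.40), Cd36 (−1.72 and −1.75) and Etfa (−0.35 and −0.27), with adjusted p-values between 0.0506 and 0.0618.

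Chaperones and folding enzymes of the endoplasmic reticulum are targets of the unfolded protein response. Most of their genes had a positive log2 fold change in refed monocytes, but a minority passed over all genes. Of 16 tested, 5 rose, 0 fell and 11 did not pass, with a median log2 fold change of 0.37 (9 rose when adjusted over the list alone). Hyou1 went from 28.1 ± 2.31 to 51.5 ± 12.8 CPM (edgeR adjusted p = 0.0199), the protein disulphide isomerase genes Pdia4 from 115 ± 8.59 to 170 ± 17.6 and Pdia6 from 324 ± 13.1 to 417 ± 40.1, and Edem1 from 518 ± 49.5 to 685 ± 38.3. After length correction Edem1 went from a log2 fold change of 0.40 to 0.15 (adjusted p = 0.4) and the gene Pdia6 from 0.36 to 0.38 (adjusted p = 0.051), and 3 of the 5 kept their call. Pdia6 also lost its call with upper-quartile scaling (adjusted p = 0.0562), library size only (0.0593), no low-count filter (0.0506) and GC correction (0.0544), and the gene Edem1 with library size only (0.0506). The camera adjusted p was 4.21e-05, and 0.506 with an estimated correlation. Oxidative phosphorylation genes had a median of −0.15, and 0 of 30 passed edgeR over all genes or over the list alone (6 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom). Without refed 3, 8 of 30 were called lower. The gene Uqcrc2 had the smallest p (log2 fold change −0.33 ± 0.09, adjusted p = 0.053) and passed with the 3 other scalings (adjusted p between 0.0263 and 0.0471). Cytosolic ribosomal protein genes had a median of −0.16, and 1 of 83, Rpl3, fell, from 290 ± 27.1 to 211 ± 10.0 CPM (0 when adjusted over the list alone). Camera called both lists lower (adjusted p = 9.3e-05 and 1.85e-06). Neither held with an estimated correlation (adjusted p = 0.681 and 0.744), and both medians moved to −0.08 and −0.07 after length correction. Of 17 glycolysis genes 1 fell, Pfkfb3, from 39.8 ± 0.56 to 31.7 ± 2.33 CPM (0 when adjusted over the list alone). The call of the gene Pfkfb3 ended with no low-count filter (adjusted p = 0.0503), length correction (0.0632) and GC correction (0.0595). That list, with a median of −0.03 (0.01 after length correction), was not called (camera adjusted p = 0.356), except without refed 3 (adjusted p = 0.0364, lower). The lysosomal cholesterol transporter gene Npc1 rose from 35.4 ± 1.45 to 49.99 ± 1.79 CPM, 1 of 22 autophagy and lysosome genes (1 over the list alone, camera adjusted p = 0.562). Its log2 fold change of 0.50 became 0.28 after length correction (adjusted p = 0.0583). Of 15 integrated stress response genes 1 fell, the folate enzyme gene Mthfd2, from 35.6 ± 1.16 to 23.7 ± 2.46 CPM (1 over the list alone, camera adjusted p = 0.909). Of the 18 FOXO and insulin-responsive genes 0 passed edgeR over all genes or over the list alone (4 at an unadjusted p under 0.05, 2 by DESeq2, 0 by limma-voom, and 1 higher and 1 lower without refed 3; camera adjusted p = 0.356), and Foxo3 had the smallest p (log2 fold change 0.55 ± 0.16, adjusted p = 0.0663). The autophagy list had a median of −0.03 and a mean of 0.03, and the stress response list a median of 0.10 with a camera direction of down. Of the 9 called genes of these 7 lists, 2 were kept without fed 1, 5 without fed 2, 0 without fed 3, 4 without refed 1, 1 without refed 2 and 8 without refed 3. The unfolded protein response genes kept 0 of their 5 calls without fed 1 or fed 3 and 1 without refed 2.

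A minority of the genes for receptors of microbial products were higher in refed monocytes. Of 24 pattern recognition receptor genes, 4 rose, 0 fell and 20 did not pass, with a median log2 fold change of 0.39 (8 rose when adjusted over the list alone). The formyl peptide receptor gene Fpr1 went from 9.11 ± 3.96 to 27.2 ± 8.55 CPM (edgeR adjusted p = 0.0286), the inflammasome sensor gene Nlrp3 from 41.3 ± 2.61 to 59.5 ± 4.88 and the peptidoglycan sensor gene Nod2 from 4.89 ± 0.16 to 8.46 ± 1.55. Cd14 was the fourth. After length correction Nod2 went from a log2 fold change of 0.79 to 0.62 and was not called (adjusted p = 0.0826). The camera adjusted p was 0.0147, 0.0538 without fed 1, 0.177 without refed 3, and 0.554 with an estimated correlation. In the list of inflammatory cytokines and NF-kB targets, 1 of 16 rose, Nlrp3 again (1 over the list alone), with a list median of −0.11 and a mean of 0.05 (camera adjusted p = 0.887). Il1b was at 35 ± 15.5 CPM in fed and 29.5 ± 13.2 in refed (adjusted p = 0.729). Of 23 immediate early and dissociation genes, Egr1 rose and the phosphatase gene Dusp2 fell, from 19.5 ± 7.82 to 7.60 ± 1.21 CPM (1 each over the list alone, camera adjusted p = 0.708). Of these 6 called genes, 1 was kept without fed 1, 3 without fed 2, 0 without fed 3, 3 without refed 1, 1 without refed 2 and 6 without refed 3.

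Markers of immature myeloid cells went both ways, and few cell cycle genes passed. Among 7 tested progenitor markers Cd93 rose, from 111 ± 19.5 to 287 ± 52.3 CPM (edgeR adjusted p = 0.00669), and Sox4 fell, from 2.17 ± 0.24 to 0.76 ± 0.43 CPM (2 rose and 2 fell when adjusted over the list alone). The list median was −0.05 (0.04 after length correction) and its mean 0.07, with a camera direction of down (adjusted p = 0.936). Of 18 cell cycle genes 1 fell, the replication helicase gene Mcm6, from 19.7 ± 0.59 to 14.5 ± 1.46 CPM (0 over the list alone). That list had a median of 0.12, a camera direction of down and a camera adjusted p of 0.707. Neutrophil markers had a median of 0.34, and 1 of 9 tested, G0s2, fell, from 3.66 ± 1.49 to 1.36 ± 0.36 CPM (2 rose and 1 fell over the list alone, camera adjusted p = 0.172). The gene G0s2 was not called with limma-voom (adjusted p = 0.074), length correction (0.069) or GC correction (0.0506), and limma-voom called 0 of the 9 (3 at an unadjusted p under 0.05 in edgeR, 2 by DESeq2). The granule protein gene Lcn2 was at 4.88 ± 5.64 CPM in fed and 36.9 ± 34.7 in refed (adjusted p = 0.0798). Of the 4 called genes, 1 was kept without fed 1, 2 without fed 2, 1 without fed 3, 2 without refed 1, 1 without refed 2 and 3 without refed 3.

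Summed transcripts of other blood cells ranged from T cell markers, at 1.29 CPM in fed and 0.69 in refed libraries, to erythroid markers, at 11004 CPM in fed and 17838 in refed. NK cell markers fell in 8 of 9 tested, with a median log2 fold change of −2.10 (9 when adjusted over the list alone). They included the perforin gene Prf1, from 2.44 ± 0.42 to 0.34 ± 0.19 CPM, the granzyme gene Gzma, from 4.08 ± 0.91 to 0.87 ± 0.28, Nkg7, from 2.10 ± 0.37 to 0.50 ± 0.26, and Klrk1, from 21.7 ± 10.0 to 6.29 ± 0.48. The camera adjusted p was 1.95e-07 (0.483 with an estimated correlation; fry adjusted p = 0.0155). Platelet markers fell in 4 of 11 (10 when adjusted over the list alone): Ppbp, from 199 ± 28.9 to 123 ± 11.3 CPM, Treml1, Alox12 and Tubb1 (camera adjusted p = 1.17e-06, and 0.483 with an estimated correlation). The platelet markers kept 0 of their 4 calls without fed 1, fed 3 or refed 2, and the gene Tubb1 was not called after length (adjusted p = 0.0856) or GC correction (0.054). Erythroid markers rose in 5 of 7 (7 over the list alone), among them the haem synthesis gene Alas2, from 162 ± 10.8 to 378 ± 108 CPM, Slc4a1, Hba-a1 and Hba-a2 (camera adjusted p = 0.000164, and 0.483 with an estimated correlation). The calls of Hba-a1 and Hba-a2, and of the gene Hbb-bs, chosen after its values were seen, were lost with upper-quartile scaling and with library size only. That of Hbb-bs was also lost with DESeq2 size factors (adjusted p = 0.0513), limma-voom (0.0544) and length correction (0.0508). Of 8 B cell markers 1 fell, Cd22, from 6.05 ± 1.42 to 2.43 ± 0.34 CPM (2 over the list alone). Their camera adjusted p was 0.0181, 0.187 without refed 3, and 0.509 with an estimated correlation. None of the 14 T cell markers reached the filter, and their highest value in any library was 0.597 CPM. Of 2 tested eosinophil and basophil markers, Siglecf and Gata2, 0 passed edgeR over all genes or over the list alone (adjusted p = 0.593 and 0.616; 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom), too few for a list test. Of 4 tested sex-linked genes 0 passed edgeR either way (1 at an unadjusted p under 0.05, 0 by DESeq2 or limma-voom), and Uty had the smallest p (log2 fold change 0.32 ± 0.13, adjusted p = 0.168). Of the 21 genes called in the NK, B cell, platelet, erythroid and dendritic cell lists, 6 were kept without fed 1, 13 without fed 2, 2 without fed 3, 8 without refed 1, 6 without refed 2 and 20 without refed 3.

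Haemoglobin transcripts made up 1.74 ± 0.55% of counts in refed and 1.08 ± 0.07% in fed libraries (SD, n = 3 each), with 2.37% in refed 1 (two-sided exact permutation p = 0.1, the smallest this design allows). Mitochondrial transcripts made up 0.44 ± 0.02% and 0.50 ± 0.04% (exact p = 0.1), ribosomal protein transcripts 0.89 ± 0.08% and 1.04 ± 0.12% (exact p = 0.2), and nuclear RNAs 0.11 ± 0.03% and 0.12 ± 0.04% (exact p = 0.7). The 10 most abundant genes took 11.8 ± 0.16% of counts in refed and 9.72 ± 0.13% in fed libraries (exact p = 0.1). The single-cell libraries, 1 per group, entered no comparison.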

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

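The length and GC corrections were chosen after the results were seen, and the other settings before. For the settings below the cause of a change was not tested, except that the 1.5-fold test, the other threshold and the left-out libraries change counts by construction. The 1189 changed genes (754 higher, 435 lower) became 1802 with DESeq2 (1178 shared), 750 of them lower. Limma-voom with quality weights gave 2593 (1497 higher, 1096 lower), a threshold of 0.1 gave 2145 (1270 and 875), and the edgeR test against a fold change of 1.5 gave 8 (6 and 2). Length correction gave 734, with 403 higher. Leaving out single libraries gave 165 to 1713 genes, 127 to 1028 higher and 38 to 685 lower, and none of the 1189 changed direction. After length correction 5 of them did. The other counts stayed within 1.5 times the main count, and the median log2 fold change of all genes moved to at most −0.05 (library size only).

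The replicate numbers did not pair the libraries, with correlations of 0.22, −0.12 and 0.00 between same-numbered libraries. A replicate block gave 907 genes, 805 of them among the 1189, and 16 lists, with the gene Ccr2 called (adjusted p = 0.0477). It kept 9 of 12 calls in the lipid lists, 5 of 9 in the energy and stress lists, 2 of 4 in the progenitor, cell cycle and neutrophil lists, 17 of 21 in the lists of other cells and 8 of the 12 abundant genes. It turned the direction of the progenitor list (adjusted p = 0.866) and the integrated stress response list (adjusted p = 0.867), neither called.

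Of the 16 lists called by camera, 0 were called with an estimated correlation (1 list at an unadjusted p under 0.05) and 2 by fry, those of NK cells and the clock. With an estimated correlation the adjusted p was 0.483 for the non-classical, NK, platelet, erythroid, dendritic cell, trafficking, interferon, MHC class II and clock lists. It was 0.509 for the B cell, cholesterol and fatty acid oxidation lists, 0.506 for the unfolded protein response, 0.554 for pattern recognition receptors, 0.681 for oxidative phosphorylation and 0.744 for ribosomal proteins. With fry it was 0.106 for the non-classical, platelet, erythroid, trafficking, interferon, MHC class II and unfolded protein response lists. It was 0.146 for B and dendritic cells, 0.159 for cholesterol, 0.128 for fatty acid oxidation, 0.347 for oxidative phosphorylation, 0.205 for pattern recognition receptors and 0.454 for ribosomal proteins. Fry also turned the direction of the progenitor (0.357), inflammatory (0.978) and fatty acid synthesis (0.95) lists, none called.

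The trafficking and clock calls ended with DESeq2 size factors (camera adjusted p = 0.0554 and 0.0531), GC correction (0.0651 each) and a filter of at least 5 CPM (0.0774 and 0.249). Length correction called the classical list (0.0362). Directions of lists not called turned for immediate early and fatty acid synthesis genes with the 5 CPM filter (0.989 each), for fatty acid synthesis and the stress response with GC correction (0.963 each), and for the stress response with length correction (0.783). With single libraries left out the camera adjusted p ran from 0.0104 to 0.496 for the classical list, 0.00600 to 0.187 for B cells, 0.00208 to 0.0638 for dendritic cells, 0.0276 to 0.267 for trafficking, 0.026 to 0.0886 for the clock, 0.000153 to 0.177 for pattern recognition receptors and 0.0364 to 0.771 for glycolysis. It ran from 0.800 to 0.964 for progenitors, 0.207 to 0.868 for glucocorticoid-induced genes, 0.145 to 0.918 for inflammatory genes, 0.188 to 0.744 for immediate early genes, 0.42 to 0.868 for fatty acid synthesis and 0.346 to 0.926 for the stress response.

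Among named genes, those that turned direction had not passed the test. Log2 fold changes were −0.031 for Cx3cr1 and −0.059 for Per1 after length correction, and −0.037 for Per1, −0.25 for Trem1 and −0.25 for Selp with quality weights. With single libraries left out they ran from −0.41 to 0.014 for Cxcr4, −0.089 to 0.28 for Cx3cr1, −0.13 to 1.22 for Fkbp5, −0.13 to 0.24 for Per1, −0.56 to 0.15 for Il1b, −0.51 to 1.88 for Trem1 and −0.51 to 1.78 for Selp. The nuclear RNA share, refed minus fed, ran from −0.0256 to 0.0091 percentage points, above 0 without fed 1 or refed 3. At this depth and number of libraries, the test on simulated counts found 29 of 67 genes changed 1.5-fold, so smaller changes were often not detectable.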

Other observations

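All tests below except that of how the non-classical markers deviate within groups were chosen after the results were seen. The 12 most abundant changed genes outside the rule for named genes were picked after their values were seen and stand for no gene group. The MHC class I heavy chain gene H2-D1 went from 4616 ± 517 to 3561 ± 156 CPM and the class I light chain gene B2m from 2177 ± 240 to 1571 ± 50.5 CPM (SD, n = 3 per group, edgeR adjusted p = 0.0475 and 0.0226). The endolysosomal protease gene Ctss went from 1988 ± 8.92 to 1476 ± 98.5 CPM (adjusted p = 0.0166). The lysosomal membrane gene Laptm5, Itm2b and Ly6e were lower as well. The actin gene Actb went from 3201 ± 392 to 4892 ± 764 CPM, the actin crosslinker gene Flna from 2710 ± 101 to 3585 ± 99.1 and the integrin activator gene Tln1 from 1389 ± 47.3 to 1991 ± 84.5 (adjusted p = 0.0293, 0.0151 and 0.00913). The apolipoprotein gene Apoe rose from 1420 ± 289 to 2785 ± 755 CPM and the pore-forming protein gene Mpeg1 from 1670 ± 129 to 2336 ± 307 (adjusted p = 0.0333 and 0.036). Hbb-bs was the remaining gene. After length correction 5 of the 12 kept their call. In the other 7 the log2 fold change went from 0.40 to 0.05 for Flna, 0.48 to 0.34 for Mpeg1, −0.27 to −0.18 for Laptm5, −0.32 to −0.23 for Itm2b, −0.41 to −0.32 for Ly6e, −0.37 to −0.29 for H2-D1 and 0.84 to 0.93 for Hbb-bs. H2-D1 also lost its call with limma-voom (adjusted p = 0.057) and GC correction (0.0516), the gene Laptm5 with no low-count filter (0.0545) and GC correction (0.0531), the gene Itm2b with limma-voom (0.0519), and the gene Mpeg1 with upper-quartile scaling (0.0506) and library size only (0.061). Of the 12, 1 was kept without fed 1, 6 without fed 2, 0 without fed 3, 3 without refed 1, 3 without refed 2 and 12 without refed 3.

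Genes higher in refed lay among long transcripts, with a median length of 3939 bases, against 1490 for genes lower in refed and 2071 for all genes tested. Across genes, which are not independent replicates, the Spearman correlation of a library's deviation with length was −0.15, −0.20 and −0.29 in the fed libraries and 0.29, 0.33 and 0.03 in the refed ones. A length trend between libraries as the whole cause is argued against by the 364 of 754 rises that stayed called after the trend was removed, and GC content by the 657 that stayed called after its removal. For the other 390 rises a length effect of library preparation and a true rise of long transcripts after refeeding cannot be told apart, because the trend goes with the groups and the correction removes it by construction. In these 390 the median log2 fold change went from 0.51 to 0.28 with the median SE at 0.10 before and 0.10 after, so the calls ended through smaller folds, and 326 of them were among the longest transcripts.

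Lars2 and Gm15564 rose together, and a candidate explanation is reads from a sequence that both share. The run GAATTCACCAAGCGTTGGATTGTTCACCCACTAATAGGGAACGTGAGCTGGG spans 52 bases in the 3′ UTR of Lars2, in its last exon of 21 (GRCm38 chromosome 9, 123462048 to 123462099, plus strand), and the junction of exons 1 and 2 of a Gm15564 transcript (chromosome 16, 35981745 to 35983052, minus strand). Of GENCODE M21 genes only 3 hold 31 bases of it, and both of those in the count table are these; the ratio of Lars2 to Gm15564 counts ran from 228 to 344 over the 6 libraries, a 1.51-fold range within counting error (chi-square p = 0.34). Mitochondrial ribosomal RNA is argued against by the longest shared run of 14 bases. Gm26917 and Gm42418, taken as transcripts of the ribosomal DNA locus, had log2 fold changes of 0.48 ± 0.21 and 0.32 ± 0.21. Neither passed (edgeR), and Lars2 lay above the first by 2.35 ± 0.29. Neither gene holds 31 bases of the run, so their levels cannot tell whether a ribosomal RNA that carries it rose. The search for the run covered annotated GENCODE M21 transcripts only, with no separate ribosomal RNA reference. Which RNA carries the run was thus not tested, and an effect of feeding on it or on Lars2 stays open.

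Non-classical monocyte markers fell although the gate was set on Ly6C-high cells. The tested NK markers together lost 6.72% of the CPM that Ace alone lost (27.7 against 412 CPM). All NK markers summed to 38.8 CPM in fed libraries, so even their full loss would have stayed far below that of Ace. This result was fixed by their level and cannot decide whether NK cells were lost. With the lengths assigned here, a transcript length trend as the whole cause is argued against by the 10 of 11 markers still called after length correction. The list median of −1.15 also lay far below the median of −0.09 in the shortest bin of genes. The call of Cd36 ended (log2 fold change −1.72 ± 0.44 before and −1.75 ± 0.45 after) as its edgeR adjusted p moved from 0.0492 to 0.0608. Within groups the called markers deviated together, with a median correlation over pairs of 0.93, against 0.85 among called MHC class II genes, 0.68 among called classical markers, 0.27 among called NK markers and 0.000573 among genes taken at even steps from all tested, and of 0.64 between non-classical markers and MHC class II genes. That is consistent with a share of non-classical monocytes among the sorted cells that varied between libraries and was lower after refeeding, but joint regulation in each cell would give the same, so these cannot be told apart, and neither can a response to feeding.

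The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For the 1189 changed genes, 1 split, the real one, gave as many, and the highest other split gave 0 genes by edgeR, with 84 to 1362 genes at an unadjusted p under 0.05 and 0 to 87 genes by DESeq2 over the 9 other splits. For the 16 lists called by camera with the preset correlation, 1 split gave as many, and the 9 other splits gave 7 to 14 of 28 lists. The preset correlation called many lists between mixed groups too. Every other split leaves fed and refed libraries unequal between its sides, so part of the real difference remains in it. Its list calls are therefore not a measure of false calls. Mixing also adds the group difference to the spread within each side, which can lower gene calls.

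Refed 3 stood apart from refed 1 and 2 across genes. Its score on the second principal component, with 25.6% of the variance, was −27.6, against 18.5 and 21.9, and its chi-square per degree of freedom against them was 53.6 and 52.2, against 14.8 between them. The genes named next were picked after their values were seen. Trem1 was at 8.92, 10.1 and 90.2 CPM in refed 1 to 3, Ccl2 at 7.70, 6.38 and 67.4, Selp at 2.74, 2.44 and 22.9 and Tarm1 at 9.05, 10.0 and 67.9, while the fed means were 13.5 ± 1.99, 6.26 ± 3.12, 3.68 ± 0.32 and 9.22 ± 4.09 CPM. None of these 4 passed the edgeR test (adjusted p = 0.3, 0.167, 0.32 and 0.208), and the log2 fold change of Trem1 was −0.51 without refed 3. The deposited barcode list of the single-cell data held 46994 barcodes under 8 suffixes, with 5364 to 6312 per suffix, and no label used here ties a suffix to the fed or the refed library.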
